A study of Homo sapiens with 8 samples.

How the data were processed

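RNA-seq was available for 8 libraries of total RNA from CAL-1 cells, an established human cell line. Per the labels, tetracycline induced the METTL3 knockout, and DMSO or 0.31 µM GSK595 followed for 72 h. The libraries formed 4 groups of 2: WT DMSO, WT GSK595, KO DMSO and KO GSK595. The labels do not say whether the WT cells also received tetracycline, or what the replicate numbers stand for.

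The deposited table of raw values holds estimated counts (expected counts) per gene symbol for 27920 genes, and 25.0% of its values above 0 were whole numbers to within 0.001. The plan had assumed whole counts, so the estimates were rounded to whole numbers before fitting. A second deposited table holds normalized signal, that is, the rounded count divided by a factor that differs between genes as well as libraries and has a geometric mean of 1 for each gene. In the deposited table of KO DMSO against WT DMSO, per the file headers, the authors give log2 fold changes with standard errors, and each p-value with an adjusted p. Salmon 1.4.0 and DESeq2 1.30.0 are named by the submitters as tools. The genome build and annotation are not given in the sources used here, so no coordinates are reported.

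Library totals lay between 109346649 and 116854679 estimated counts, and 19036 genes had a count in any library. The 14855 genes that passed filterByExpr (minimum count 10, minimum total 15) were tested with edgeR 4.0.16 in R 4.3.3. One fit over all 8 libraries had a term for each group, TMM scaling and a quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjusted p below 0.05 as the threshold. The residual degrees of freedom were 4, the prior degrees of freedom 4.36 and the common dispersion 0.022. Log2 fold changes used a prior count of 0.125 and log2 CPM a prior count of 2. The SE given with a log2 fold change is its size divided by the square root of its F statistic. It restates the test and is not a separate estimate of the spread. Levels are TMM-scaled CPM. Intervals of count ratios are exact Clopper-Pearson intervals at 95% and cover counting error only. Intervals of list medians come from order statistics over the genes of a list, and that of a difference of 2 lists from resampling genes. They treat genes as independent and do not cover the spread between libraries. A gene with 3 counts or fewer over a group was taken as near the floor.

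The comparisons were KO against WT in DMSO, GSK595 against DMSO in WT and in KO cells, KO against WT in GSK595, and the interaction of KO and GSK595. The 30 gene lists with at least 5 tested members were tested by camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in one direction, were run beside it. The estimated version raised p also for a list whose members were barely correlated, so it is the stricter test in that case too. Counts of list members are given over all genes tested and adjusted over the list alone. The groups, the comparisons, the tests, the gene lists, the rule for naming genes and the other settings to be tried were fixed before the data were examined.

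METTL3 and PRMT5 could be named in every comparison. Otherwise, genes were named by rule among those past the threshold with a mean of at least 5 CPM and no overlap between the groups (no overlap rule for the interaction): the 5 largest rises and 5 largest falls (3 and 3 for the interaction), and the 4 members with the smallest adjusted p of each list that camera called or that had at least 4 members past the threshold. Members past the threshold of the m6A and PRMT5 complex lists could be named as well.

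Replicate numbers were checked for pairing. The deviations of replicate 1 from its group mean correlated across genes between all 6 pairs of groups, at 0.109 to 0.268, so the counts with the replicate number as a block are given beside results that it moves. The test was checked on simulated data built on KO against WT in DMSO with 200 changed genes: 80% were recovered at a log2 fold change of 1 and 99% at 2, and 15 unchanged genes were called. Camera gave an adjusted p of 2.64e-42 for a simulated list of 30 raised genes and 0.868 for a list of 30 unchanged genes. The simulated genes were drawn independently, so this does not check camera on lists whose members are correlated. A gene had the same dispersion in every simulated group, and only genes with a mean of at least 1 CPM were changed. The recovery and the calls of unchanged genes therefore do not cover a group whose replicates differ more, as the WT DMSO replicates did. Recovery of genes at lower levels was not checked.

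The other settings tried were DESeq2 1.42.0, RLE size factors, no filter and a stricter filter on low counts (1 CPM in each library of a group), the replicate block, a log2 fold change of at least 1, thinning to the shallowest library, the groups compared alone, and leaving out each library in turn, in which the lone library is assumed to vary like the other groups. Gene-wise factors taken from the deposited normalized table, and the list tests under those factors and without each library, were added after the data had been seen. A gene without a count in some library took the median factor of each library in place of its own. Groups of 2 allowed no outlier test and no test by regrouping of the libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.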

Results

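RNA was sequenced from CAL-1 cells, an established line derived from a blastic plasmacytoid dendritic cell neoplasm, a leukemia of the plasmacytoid dendritic cell lineage. The cells were either wild type (WT) or carried an induced knockout (KO) of METTL3, the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on RNA. Both were kept for 72 h in DMSO, the solvent, or in 0.31 µM GSK595, a compound known by its code name that inhibits the arginine methyltransferase PRMT5. The 4 groups held 2 libraries each, so that n = 2 for every group mean below. Total estimated counts per library lay between 109346649 and 116854679, and 14855 of 27920 genes had enough counts to be tested. The question was how loss of METTL3, inhibition of PRMT5 and both together changed gene expression. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

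METTL3 itself was examined first, since it is the gene targeted. Its level was 37.9 and 32.0 CPM (TMM-scaled) in the WT DMSO libraries, 29.6 and 27.5 in WT GSK595, 30.2 and 28.9 in KO DMSO, and 27.1 and 27.0 in KO GSK595. In DMSO the KO had 29.6 ± 0.925 CPM and the WT 35.0 ± 4.19 CPM (SD, n = 2), a log2 fold change of -0.24 ± 0.11 SE with an adjusted p of 0.148 (edgeR quasi-likelihood test, Benjamini-Hochberg). The difference did not pass the test, and without WT DMSO replicate 2 it did (-0.34, adjusted p 0.0453). A count over the whole gene can stay high after an edit that ends the protein, and the labels do not say where the edit lies, so the METTL3 level does not check the KO label. PRMT5, the target of GSK595, stood at 124 ± 27.4 CPM in WT DMSO, 136 ± 8.08 in WT GSK595, 120 ± 10.9 in KO DMSO and 91.7 ± 10.3 in KO GSK595 (SD, n = 2).

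**Figure D1:**
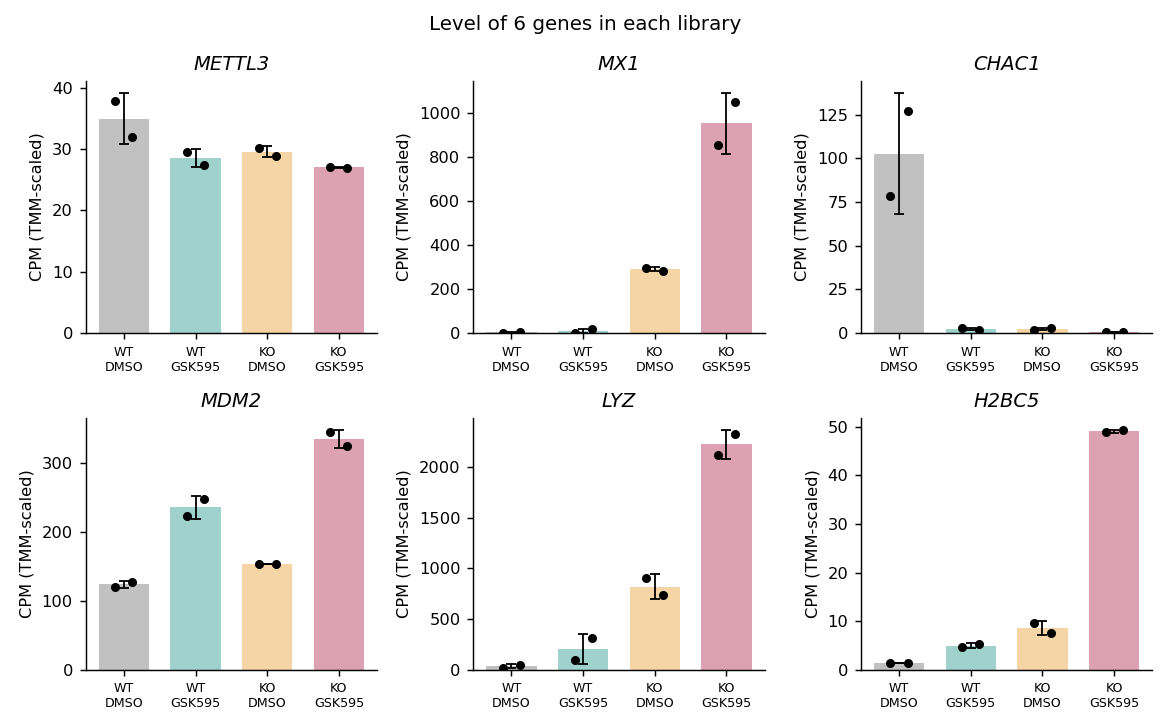
TMM-scaled CPM of 6 genes, with a point for each of the 8 libraries, a bar for each group mean and an error bar of 1 SD (n = 2). METTL3 lies between 27.0 and 37.9 CPM in every library, while MX1 averages 3.22 CPM in WT DMSO and 954 CPM in KO GSK595, and CHAC1 averages 103 CPM in WT DMSO and 0.719 CPM in KO GSK595.

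In DMSO, the KO cells had far higher levels of interferon response genes than the WT cells, far lower levels of integrated stress response genes, more transcript of monocyte and dendritic cell markers, and less of mitotic genes. Among the largest rises were IFI44L (log2 fold change 8.0 ± 1.12 SE), MX1 (6.50 ± 0.88 SE), MX2 (5.98 ± 0.39 SE) and EPSTI1 (5.69 ± 0.65 SE), which interferon induces. FSCN1 also rose (7.14 ± 0.80 SE), a gene for an actin-bundling protein of mature dendritic cells. The largest falls included INHBE (-6.76 ± 0.76 SE), the glutathione-degrading enzyme gene CHAC1 (-5.44 ± 0.34 SE), ADM2 (-4.52 ± 0.55 SE) and JDP2 (-3.60 ± 0.57 SE), with adjusted p between 0.000144 and 0.0031 (edgeR). MEF2B also fell (-4.48 ± 1.27 SE), but it shares reads with an overlapping readthrough transcript and its call was lost without KO DMSO replicate 1 (adjusted p 0.165), KO DMSO replicate 2 (0.145) or WT DMSO replicate 2 (0.172, log2 fold change -2.53), and in DESeq2 (0.107). In all, 2195 genes rose and 2070 fell, of which 746 and 469 had a log2 fold change of at least 1 in size. IFI44L was at 12.03 without WT DMSO replicate 2. The 4265 changed genes became 1703 without KO DMSO replicate 1 and 1822 without KO DMSO replicate 2, and 2752 with only the 4 DMSO libraries in the fit.

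Of 35 tested genes of the type I interferon response, 34 rose and 0 fell in KO DMSO (35 and 0 adjusted over the list alone), with a median log2 fold change of 3.01 and a camera adjusted p of 2.78e-19. With an estimated correlation in place of the preset one, that call was lost (camera adjusted p = 0.584). By fry the interferon list passed (adjusted p 0.00356). A loss with an estimated correlation need not come from correlated members. For GSK595 in WT, the p53 list had an estimated correlation of -0.0099, below the preset 0.01. Its unadjusted camera p still went from 5.5e-09 to 0.0027. Of the 12 lists that camera called for KO in DMSO, fry called 10 in the same direction. IFIT1 rose by 5.84 ± 0.24 SE on the log2 scale, OAS2 by 4.84 ± 0.29 SE and the RNA sensor gene DDX58 by 2.37 ± 0.14 SE (edgeR adjusted p 6.7e-05 to 0.000137). Antigen presentation genes moved the same way. Of 15 tested genes of MHC class II presentation 12 rose and 0 fell (12 and 0 adjusted over the list alone; median 0.99, camera adjusted p 5.83e-07). Among them were CIITA, the transcriptional activator of the class (1.39 ± 0.17 SE), and the invariant chain CD74 (1.11 ± 0.13 SE). For MHC class I, 8 of 14 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.50, camera adjusted p 0.00234), with TAP1, a peptide transporter subunit, at 1.32 ± 0.11 SE. Both class calls had an adjusted p = 0.629 with an estimated correlation, and 5 class I genes rose without KO DMSO replicate 2. Reads of HLA genes can be divided between near-identical copies, so single HLA values are uncertain.

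Markers of monocytes, macrophages and conventional dendritic cells followed: 18 of 25 rose and 2 fell (19 and 2 adjusted over the list alone; median 1.44, camera adjusted p 9.69e-07; adjusted p = 0.629 with an estimated correlation). They included CX3CR1 (5.10 ± 0.65 SE), the lysozyme gene LYZ (4.58 ± 0.56 SE), the migration receptor CCR7 (3.53 ± 0.32 SE) and the macrophage growth factor receptor CSF1R (3.19 ± 0.27 SE). Targets of NF-kB showed 18 rises and 2 falls among 30 (20 and 2 adjusted over the list alone; median 0.69, or 0.68 with genes near the floor at their bound; camera adjusted p 4.01e-05; adjusted p = 0.707 with an estimated correlation). NFKBIE stood at 1.35 ± 0.13 SE and the chemokine CCL22 at 5.09 ± 0.70 SE. Of 27 immediate early and AP-1 genes 13 rose and 3 fell (15 and 3 adjusted over the list alone; median 0.63, camera adjusted p 0.0023; adjusted p = 0.584 with an estimated correlation), JUNB by 1.61 ± 0.13 SE and KLF4 by 1.91 ± 0.17 SE. Without KO DMSO replicate 1 or KO DMSO replicate 2, 10 and 10 myeloid markers rose and 0 fell in both, and 7 and 9 NF-kB targets rose with 0 falls. Without WT DMSO replicate 2, 1 myeloid marker and 0 NF-kB targets fell.

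Genes of the integrated stress response, the programme driven by ATF4, were lower in KO DMSO: 0 of 30 rose and 27 fell (0 and 27 adjusted over the list alone), with a median log2 fold change of -1.77 and a camera adjusted p of 1.14e-11 (adjusted p = 0.629 with an estimated correlation). Examples were SESN2 (-3.44 ± 0.35 SE), the asparagine synthetase gene ASNS (-2.28 ± 0.26 SE) and VLDLR (-2.04 ± 0.20 SE). The 2 WT DMSO libraries stood apart from each other on this list, at a mean of 6.52 and 7.62 log2 CPM, and the other 6 libraries lay between 5.10 and 5.45. Without WT DMSO replicate 2, 1 gene of the list rose and 26 fell. These replicates also differed most over all genes, with a chi-square per degree of freedom of 189 against 43.0 to 58.9 in the other groups.

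Mitotic genes were lower as well: 0 of 40 genes of G2/M and mitosis rose and 26 fell (0 and 32 adjusted over the list alone; median -0.44, camera adjusted p 9.56e-09; adjusted p = 0.629 with an estimated correlation). Among them were the condensin subunit NCAPG (-1.07 ± 0.14 SE), NUSAP1 (-0.77 ± 0.11 SE), the checkpoint kinase BUB1B (-0.72 ± 0.11 SE) and AURKB (-0.62 ± 0.09 SE). Cytosolic ribosomal protein genes fell in 21 of 77 cases and rose in 0 (0 and 21 adjusted over the list alone; median -0.20, camera adjusted p 3.75e-07; adjusted p = 0.721 with an estimated correlation). RPL24 stood at -0.61 ± 0.10 SE. Their many pseudogenes make single values uncertain. Replication-dependent histone genes rose in 15 of 46 cases and fell in 0 (15 and 0 adjusted over the list alone; median 0.68, camera adjusted p 5.64e-05; adjusted p = 0.584 with an estimated correlation). H3C10 stood at 2.68 ± 0.21 SE, H2BC5 at 2.62 ± 0.16 SE and H1-2 at 2.11 ± 0.15 SE, all from a family of near-identical copies. The mean over the histone list was low in every library, from -2.148 log2 CPM in WT DMSO replicate 1 to -0.6565 in KO GSK595 replicate 1. Rises of this list in any comparison therefore concern, on average, small amounts of histone transcript. Without KO DMSO replicate 1 or KO DMSO replicate 2, 8 and 7 mitotic genes fell, and 2 and 6 ribosomal protein genes. Of the latter, 13 fell without WT DMSO replicate 1, and 6 histone genes rose without KO DMSO replicate 1.

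Smaller shifts were seen in DNA replication and repair. Of 40 genes of G1/S and DNA replication 12 fell and 2 rose (14 and 3 adjusted over the list alone; median -0.19, camera adjusted p 0.0236; adjusted p = 0.781 with an estimated correlation). Of 35 genes of the Fanconi and homologous recombination pathways 10 fell and 2 rose (11 and 2 adjusted over the list alone; median -0.19, camera adjusted p 0.0223; adjusted p = 0.721 with an estimated correlation). RFC4, a clamp loader subunit, fell (-0.76 ± 0.09 SE), while the flap endonuclease FEN1 (1.32 ± 0.24 SE) and BRCA2 (0.92 ± 0.09 SE) rose. Both list calls were lost without KO DMSO replicate 2 (adjusted p 0.14 and 0.108, with 2 and 2 falls) and without WT DMSO replicate 1 (0.634 and 0.3). There were 5 and 5 falls without KO DMSO replicate 1. In that last case 1 replication gene rose, and 6 replication and 4 repair genes rose without WT DMSO replicate 1; 1 repair gene rose without KO DMSO replicate 2.

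Of the 21 genes of the m6A machinery 10 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.16), and the list as a whole did not pass (camera adjusted p 0.0648). The m6A readers YTHDF2 (1.23 ± 0.13 SE) and YTHDF1 (0.60 ± 0.10 SE) and the methyltransferase adaptors RBM15 (0.92 ± 0.16 SE) and RBM15B (0.76 ± 0.11 SE) rose. The list passed with gene-wise scaling factors (adjusted p 0.0371), without KO DMSO replicate 2 (0.0254, 7 rises) and without WT DMSO replicate 1 (0.0472), and 4 genes rose and 0 fell without KO DMSO replicate 1. PRMT6, an arginine methyltransferase, rose by 0.95 ± 0.11 SE, and PRMT5 did not pass (-0.05 ± 0.16 SE, adjusted p 0.842).

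The authors' deposited table covers this comparison and no other. By its own adjusted p, 2407 genes were higher and 2150 lower in the KO, 4557 of the 15076 genes with an adjusted p given in the authors' deposited table. Of the genes called here, 4033 were also called there in the same direction and 0 in the opposite one, 232 were called here alone, and 521 tested genes were called in the authors' deposited table alone. Across genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and those computed here had a Pearson r of 0.823. Whether the deposited fold changes were shrunken is not stated. Among the genes named for this comparison MEF2B differed most, at -0.08 there and at -4.48 here. Others lay closer, such as CHAC1 (-5.42 there and -5.44 here) and IFI44L (7.18 there and 8.0 here). The deposited MEF2B value had an SE of 0.386 and an adjusted p of 0.111, too small a p for that fold change and SE. DESeq2 run here gave MEF2B a log2 fold change of -4.48 and an adjusted p of 0.107. Shrinkage after the test would leave such values, so the MEF2B gap need not be a disagreement of the tests.

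**Figure D2:**
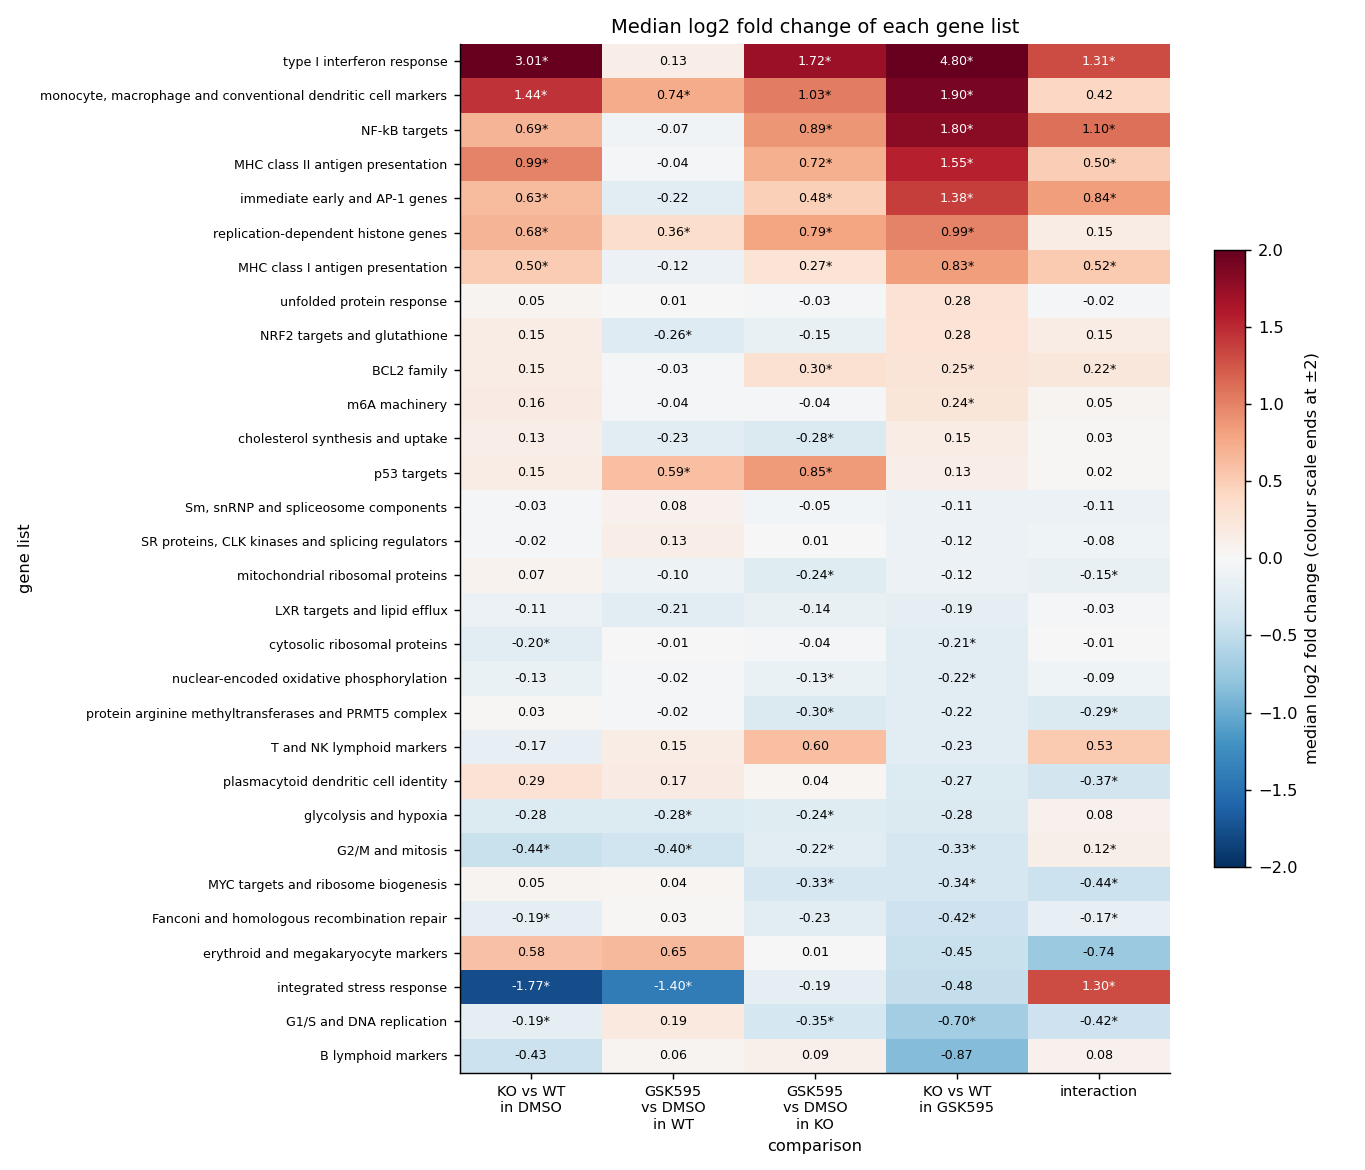
Median log2 fold change of the tested members of each of 30 gene lists (vertical axis) in each of 5 comparisons (horizontal axis), with an asterisk where the camera test with a preset correlation passed. The type I interferon list has the largest medians, 3.01 for KO in DMSO and 4.80 for KO in GSK595, against 0.13 for GSK595 in WT cells.

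In WT cells, GSK595 was followed by higher p53 target genes and by lower genes of the integrated stress response. By fry only the p53 (adjusted p 0.00443) and histone (0.039) lists passed. The stress response (0.069) and G2/M (0.12) lists did not pass by fry. The compound raised FCER1A, a chain of the IgE receptor (log2 fold change 2.59 ± 0.25 SE, edgeR adjusted p 0.00306), and CHAC1 (-5.53 ± 0.34 SE, adjusted p 0.00176) and INHBE (-5.90 ± 0.72 SE, adjusted p 0.00527) were among the largest falls. In all, 791 genes rose and 842 fell, of which 229 and 225 had a log2 fold change of at least 1 in size. The total of 1633 was 519 without WT GSK595 replicate 1, 91 without WT GSK595 replicate 2 and 3262 without WT DMSO replicate 1. It was 2799 with the replicate number as a block, 2552 in DESeq2 and 77 with the 4 WT libraries alone. The rises of KLHL4 (3.36 ± 0.64 SE), DCANP1 (2.78 ± 0.61 SE), SIGLEC1 (2.67 ± 0.52 SE) and LYZ (2.58 ± 0.51 SE), and the falls of ADM2 (-4.39 ± 0.54 SE), DDIT3 (-3.26 ± 0.47 SE) and JDP2 (-3.24 ± 0.56 SE), were lost without WT GSK595 replicate 2, with adjusted p of 0.0866, 0.165 (log2 fold change 1.69), 0.123, 0.11 (log2 fold change 1.53), 0.0688, 0.086 and 0.0848. KLHL4 was lost also without WT GSK595 replicate 1 (0.0652) and DCANP1 without WT DMSO replicate 2 (0.095), where DDIT3 stood at -2.15. With the 4 WT libraries alone in the fit, INHBE (0.0502), KLHL4 (0.0658), DCANP1 (0.0883), SIGLEC1 (0.0859), LYZ (0.0908), DDIT3 (0.0616) and JDP2 (0.0731) were lost.

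Of 29 p53 targets 18 rose and 1 fell (19 and 1 adjusted over the list alone), with a median log2 fold change of 0.59 and a camera adjusted p of 5.52e-08 (adjusted p = 0.082 with an estimated correlation). The rises included PLK2 (2.36 ± 0.26 SE), ZMAT3 (1.56 ± 0.15 SE), the nuclease gene AEN (0.99 ± 0.13 SE) and MDM2, the p53 ubiquitin ligase (0.93 ± 0.09 SE). MDM2 went from 124 ± 4.53 CPM to 235 ± 16.9 CPM (SD, n = 2). Without WT GSK595 replicate 1 and WT GSK595 replicate 2, 9 and 4 targets rose, and 4 fell without WT DMSO replicate 1 and 0 without WT GSK595 replicate 2. AEN was lost with the 4 WT libraries alone in the fit (0.0582).

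The integrated stress response list fell in 27 of 30 members and rose in 0 (28 and 0 adjusted over the list alone; median -1.40, camera adjusted p 8.32e-15; adjusted p = 0.911 with an estimated correlation). CHAC1 fell from 103 ± 34.6 CPM to 2.22 ± 0.617 CPM (SD, n = 2), and DDIT4 (-2.79 ± 0.35 SE) and the transcription factor gene ATF3 (-2.26 ± 0.25 SE) fell with it. Again both WT DMSO libraries, at 6.52 and 7.62 mean log2 CPM, lay above the WT GSK595 libraries at 5.45 and 5.29. Of the G2/M and mitosis genes 15 of 40 fell and 0 rose (23 and 0 adjusted over the list alone; median -0.40, camera adjusted p 7.4e-09; adjusted p = 0.911 with an estimated correlation). Among them were the cyclin gene CCNB1 (-0.58 ± 0.09 SE) and the phosphatase gene CDC25C (-1.06 ± 0.18 SE). Without WT GSK595 replicate 1 and WT GSK595 replicate 2, 12 and 3 stress response genes and 0 and 0 mitotic genes fell. CCNB1 then had an adjusted p of 0.0559 and 0.0847 and CDC25C of 0.0737 and 0.0926. With the 4 WT libraries alone they were at 0.0653 and 0.075. In contrast, 23 mitotic genes fell without WT DMSO replicate 1 and 8 without WT DMSO replicate 2.

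Further lists passed with calls that rested on single libraries. Histone genes rose in 8 of 46 cases and fell in 0 (9 and 0 adjusted over the list alone; median 0.36, camera adjusted p 0.012; adjusted p = 0.871 with an estimated correlation). H2BC5 stood at 1.84 ± 0.15 SE. The call was lost without WT DMSO replicate 1 (0.0998) and WT GSK595 replicate 1 (0.0811, 3 rises). There were 5 and 3 rises without WT DMSO replicate 2 and WT GSK595 replicate 2. Among monocyte, macrophage and conventional dendritic cell markers 6 of 25 rose and 1 fell (7 and 2 adjusted over the list alone; median 0.74, camera adjusted p 0.012; adjusted p = 0.951 with an estimated correlation). CSF1R stood at 2.71 ± 0.26 SE. That call was lost without WT DMSO replicate 1 (0.418, 4 falls) and WT GSK595 replicate 2 (0.0512, 2 rises and 0 falls). Genes of glycolysis and hypoxia fell in 7 of 29 cases and rose in 0 (9 and 0 adjusted over the list alone; median -0.28, camera adjusted p 0.00449; adjusted p = 0.951 with an estimated correlation). The glucose transporter gene SLC2A3 stood at -1.65 ± 0.19 SE. Without WT DMSO replicate 1 that call was lost (0.702, 5 rises and 5 falls), and 1 fell without WT GSK595 replicate 2. NRF2 targets fell in 3 of 18 cases (4 adjusted over the list alone; median -0.26, camera adjusted p 0.041; adjusted p = 0.912 with an estimated correlation). Its call was lost without WT DMSO replicate 1 (0.118, 7 falls), WT DMSO replicate 2 (0.0706) or WT GSK595 replicate 1 (0.266, 0 falls). There were 0 falls also without WT GSK595 replicate 2.

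The interferon list did not pass in WT cells under GSK595: 5 of 35 rose and 4 fell (6 and 5 adjusted over the list alone; median 0.13, camera adjusted p 0.774). TRIM22 (1.63 ± 0.16 SE) and SAMD9L (2.48 ± 0.37 SE) rose. IFIT1 had 34 counts in the WT DMSO libraries and 3 in WT GSK595, a ratio of 0.0898 (95% interval of the counts 0.0177 to 0.286). Without WT GSK595 replicate 1 the list passed as higher (0.00127, 8 rises and 1 fall). There were 7 falls without WT DMSO replicate 1; 2 fell without WT DMSO replicate 2, and 3 rose and 0 fell without WT GSK595 replicate 2. IFIT1 lost its call without WT GSK595 replicate 1 (0.0603) and WT GSK595 replicate 2 (0.0836). With the 4 WT libraries alone, IFIT1 (0.0945) and SAMD9L (0.0616) were lost.

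In KO cells, GSK595 raised most interferon response genes further and more than 1 in 3 of the p53 targets, NF-kB targets and myeloid markers tested. By camera with the preset correlation 9 lists were called as higher and 8 as lower, and 1 of the 17 kept its call with an estimated correlation. The histone gene H2BC21 rose by 3.30 ± 0.20 SE on the log2 scale (edgeR adjusted p 0.000575). PAPLN (-2.42 ± 0.19 SE), PGGHG (-2.05 ± 0.32 SE), the argininosuccinate synthetase gene ASS1 (-2.04 ± 0.24 SE) and SLC9A3R2 (-1.92 ± 0.22 SE) fell most. So did ANKHD1-EIF4EBP3 (-1.94 ± 0.34 SE), a readthrough whose reads are shared with its parts. In all, 1274 genes rose and 1275 fell, of which 408 and 222 had a log2 fold change of at least 1 in size. The total of 2549 was 628 without KO DMSO replicate 1, 309 without KO DMSO replicate 2, 774 without KO GSK595 replicate 1 and 607 without KO GSK595 replicate 2. It was 3966 with the replicate number as a block and 3995 with the 4 KO libraries alone. Of the other large rises, IL7R (3.59 ± 0.70 SE), SIGLEC1 (2.91 ± 0.49 SE) and IFI27 (2.87 ± 0.52 SE) were lost without KO DMSO replicate 1 (adjusted p 0.0989, 0.0649 and 0.0795), KO DMSO replicate 2 (0.0847, 0.0752 and 0.0832) and KO GSK595 replicate 2 (0.0821, 0.0509 and 0.0754). NR4A3 (3.22 ± 0.51 SE) was lost without KO DMSO replicate 1 (0.057) or KO DMSO replicate 2 (0.0653), and ANKHD1-EIF4EBP3 without KO GSK595 replicate 2 (0.0664); it stood at -1.26 without KO DMSO replicate 1.

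Of 29 p53 targets 17 rose and 0 fell in KO cells under GSK595 (25 and 0 adjusted over the list alone; median 0.85, camera adjusted p 7.82e-11), and this list kept its call at an adjusted p = 0.0435 with an estimated correlation. PLK2 rose by 2.22 ± 0.25 SE, the antiproliferative gene BTG2 by 1.17 ± 0.10 SE, MDM2 by 1.12 ± 0.09 SE and the ribonucleotide reductase gene RRM2B by 1.02 ± 0.09 SE. The interferon list rose in 28 of 35 members and fell in 0 (31 and 0 adjusted over the list alone; median 1.72, camera adjusted p 1.71e-14; adjusted p = 0.509 with an estimated correlation). IFIT1 stood at 2.41 ± 0.17 SE, DDX58 at 1.91 ± 0.14 SE, SAMD9 at 1.60 ± 0.09 SE and SP110 at 1.22 ± 0.09 SE. MX1 went from 290 ± 8.49 CPM to 954 ± 138 CPM (SD, n = 2). Without KO DMSO replicate 1, KO DMSO replicate 2, KO GSK595 replicate 1 and KO GSK595 replicate 2 in turn, 7, 7, 10 and 9 p53 targets and 16, 11, 25 and 17 interferon genes rose.

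NF-kB targets rose in 17 of 30 cases and fell in 0 (18 and 0 adjusted over the list alone; median 0.89, camera adjusted p 1.88e-08; adjusted p = 0.564 with an estimated correlation). REL stood at 0.96 ± 0.10 SE and the inhibitor gene TNFAIP3 at 0.93 ± 0.10 SE. Myeloid markers rose in 9 of 25 cases and fell in 1 (15 and 1 adjusted over the list alone; median 1.03, camera adjusted p 1.43e-05; adjusted p = 0.636 with an estimated correlation), CCR7 by 2.69 ± 0.29 SE and FCER1A by 2.51 ± 0.25 SE. Histone genes rose in 7 of 46 cases and fell in 0 (5 and 0 adjusted over the list alone; median 0.79, camera adjusted p 0.00117; adjusted p = 0.375 with an estimated correlation). H2BC5 stood at 2.52 ± 0.15 SE and H3C10 at 1.91 ± 0.18 SE. Most of these transcripts lack a poly(A) tail, and the share of ribosomal RNA in the counts was higher too, at 2.18% and 2.28% in KO GSK595 against 1.56% and 1.73% in KO DMSO. It was 1.61% and 1.99% in WT DMSO and 1.93% and 1.98% in WT GSK595, so the histone rise for KO in DMSO came without a higher share. MHC class II genes rose in 6 of 15 cases and fell in 0 (8 and 1 adjusted over the list alone; median 0.72, camera adjusted p 0.006; adjusted p = 0.719 with an estimated correlation). For MHC class I, 5 of 14 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.27, camera adjusted p 0.0102; adjusted p = 0.636 with an estimated correlation). TAP1 stood at 1.13 ± 0.10 SE. Without KO DMSO replicate 1, KO DMSO replicate 2, KO GSK595 replicate 1 and KO GSK595 replicate 2 in turn, the rises numbered 6, 3, 8 and 6 for NF-kB targets, 2, 2, 4 and 3 for myeloid markers, 4, 3, 4 and 4 for histones, 0, 0, 7 and 3 for class II and 1, 1, 3 and 1 for class I, and 0 myeloid markers fell in any of them. Class II had 1 fall and a median of 0.28 without KO GSK595 replicate 2, and class I had 0 falls without KO DMSO replicate 1, KO DMSO replicate 2 or KO GSK595 replicate 1.

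Immediate early and AP-1 genes rose in 10 of 27 cases and fell in 1 (10 and 1 adjusted over the list alone; median 0.48, camera adjusted p 0.000198; adjusted p = 0.375 with an estimated correlation). In the BCL2 family 8 of 18 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.30, camera adjusted p 0.018; adjusted p = 0.509 with an estimated correlation). With KO DMSO replicate 1, KO DMSO replicate 2, KO GSK595 replicate 1 and KO GSK595 replicate 2 left out in turn, 2, 1, 4 and 3 immediate early genes and 2, 0, 4 and 3 of the BCL2 family rose, and 0 of the latter fell in any of them. The BCL2 median was 0.51 without KO GSK595 replicate 1.

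In each of the 8 lists called as lower, most members did not pass. Among genes of G1/S and DNA replication 12 of 40 fell and 0 rose (15 and 0 adjusted over the list alone; median -0.35, camera adjusted p 4.47e-06; adjusted p = 0.719 with an estimated correlation). The replication complex gene GINS4 stood at -0.97 ± 0.12 SE. MYC targets and ribosome biogenesis genes fell in 12 of 35 cases and rose in 1 (16 and 1 adjusted over the list alone; median -0.33, camera adjusted p 5.89e-06; adjusted p = 0.719 with an estimated correlation), MYC itself being at -1.24 ± 0.14 SE. Mitochondrial ribosomal protein genes fell in 11 of 48 cases and rose in 0 (19 and 0 adjusted over the list alone; median -0.24, camera adjusted p 1.19e-06; adjusted p = 0.509 with an estimated correlation). Nuclear-encoded genes of oxidative phosphorylation fell in 7 of 52 (7 adjusted over the list alone; median -0.13, camera adjusted p 0.006; adjusted p = 0.757 with an estimated correlation), the ATP synthase gene ATP5F1D being at -0.97 ± 0.12 SE. Without KO DMSO replicate 1, KO DMSO replicate 2, KO GSK595 replicate 1 and KO GSK595 replicate 2 in turn, 2, 2, 4 and 3 replication genes fell, 1, 1, 3 and 1 MYC targets (with 0 rises in each), 2, 0, 2 and 4 mitochondrial ribosomal genes and 3, 2, 2 and 3 oxidative phosphorylation genes. The other 4 had fewer falls. G2/M and mitosis genes fell in 6 of 40 cases (6 adjusted over the list alone; median -0.22, camera adjusted p 9.05e-05; adjusted p = 0.719 with an estimated correlation), arginine methyltransferases and the PRMT5 complex in 3 of 14 (4 adjusted over the list alone; median -0.30, camera adjusted p 0.0105; adjusted p = 0.73 with an estimated correlation). Genes of glycolysis and hypoxia fell in 6 of 29 cases and rose in 2 (10 and 2 adjusted over the list alone; median -0.24, camera adjusted p 0.0308; adjusted p = 0.773 with an estimated correlation). Cholesterol genes fell in 2 of 24 cases (1 adjusted over the list alone; median -0.28, camera adjusted p 0.0399; adjusted p = 0.836 with an estimated correlation). With the same 4 libraries left out in turn, 0, 0, 3 and 0 G2/M genes fell, 2, 0, 0 and 0 of glycolysis (with 1 rise in each) and 0, 0, 0 and 1 cholesterol genes, and none of the PRMT5 complex list. The G2/M call was lost without KO GSK595 replicate 2 (0.05004) and its median was -0.37 without KO GSK595 replicate 1. The glycolysis call was lost without KO DMSO replicate 2 (0.0714) or KO GSK595 replicate 2 (0.152). The cholesterol call was lost without KO DMSO replicate 1 (0.204, median -0.17) or KO GSK595 replicate 2 (0.105) and with gene-wise scaling factors (0.0586).

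PRMT5 did not pass in KO cells under GSK595 (-0.38 ± 0.16 SE, adjusted p 0.128) and passed with the replicate number as a block (-0.39, adjusted p 0.0206) and with the 4 KO libraries alone (-0.39, 0.0316). The integrated stress response list did not pass either, 2 of 30 rising and 5 falling (2 and 6 adjusted over the list alone; median -0.19, camera adjusted p 0.166). With KO DMSO replicate 1, KO DMSO replicate 2, KO GSK595 replicate 1 and KO GSK595 replicate 2 left out in turn, 0, 0, 1 and 0 rose and 2, 1, 1 and 1 fell.

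**Figure D3:**
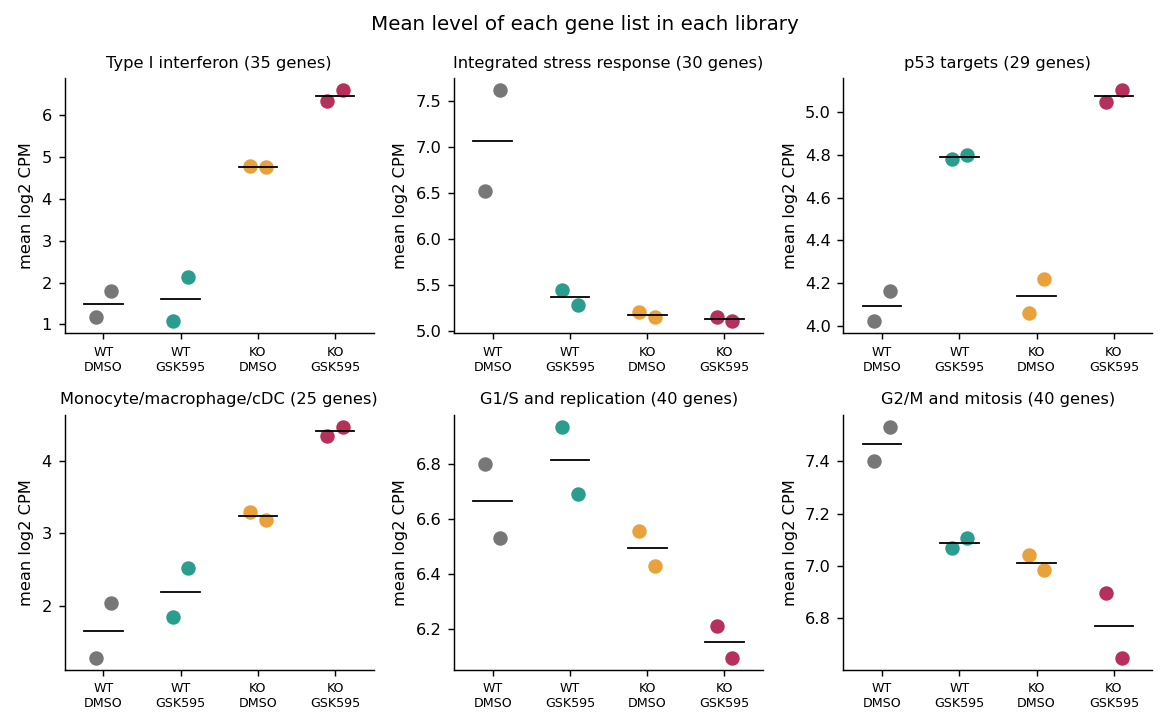
Mean log2 CPM over the tested members of 6 gene lists in each library, with a point per library and a line at each group mean (n = 2). Interferon genes average 4.75 and 4.78 log2 CPM in the KO DMSO libraries and 1.17 and 1.80 in WT DMSO, and stress response genes lie at 6.52 and 7.62 in WT DMSO and at 5.45 or lower in the other 6 libraries.

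With GSK595 present in both genotypes, the KO differed from the WT most widely. The largest rises were interferon-induced: MX2 (log2 fold change 8.05 ± 0.42 SE), IFI44L (7.71 ± 1.03 SE), IFI44 (7.37 ± 0.43 SE) and IFI6 (7.31 ± 0.77 SE). IFIT1 had 9581 counts in the KO GSK595 libraries and 3 in WT GSK595, a ratio of 3410 (95% interval of the counts 1167 to 16540). Largest among the falls were ASS1 (-3.24 ± 0.25 SE), ADAMTS18 (-2.94 ± 0.24 SE), PAPLN (-2.88 ± 0.19 SE), C16orf74 (-2.83 ± 0.17 SE) and the chemokine receptor gene CCR2 (-2.74 ± 0.18 SE), all with an edgeR adjusted p between 3.47e-05 and 0.000119. In all, 2650 genes rose and 2499 fell, of which 1111 and 516 had a log2 fold change of at least 1 in size. Of the genes called for the KO in DMSO and in GSK595, 1579 rose in both, against 392 for independent lists, and 1318 fell in both, against 348. The total of 5149 was 3300 without KO GSK595 replicate 1, 2975 without KO GSK595 replicate 2, 2487 without WT GSK595 replicate 1 and 3360 without WT GSK595 replicate 2. PRMT5 passed in this comparison (-0.57 ± 0.16 SE, adjusted p 0.023) and was lost without KO GSK595 replicate 2 (0.146), WT GSK595 replicate 1 (0.132) or WT GSK595 replicate 2 (0.0611).

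Every one of the 35 tested interferon genes rose (35 adjusted over the list alone; median 4.80, camera adjusted p 2.36e-23; adjusted p = 0.431 with an estimated correlation), as they did without each of the 4 libraries in turn. NF-kB targets rose in 27 of 30 cases and fell in 0 (29 and 0 adjusted over the list alone; median 1.80, camera adjusted p 9.81e-13). TRAF1 stood at 3.32 ± 0.20 SE. Myeloid markers rose in 20 of 25 cases and fell in 0 (21 and 0 adjusted over the list alone; median 1.90, camera adjusted p 1.31e-08). CCR7 stood at 5.48 ± 0.34 SE and CD83 at 2.91 ± 0.31 SE. The calls of these NF-kB and myeloid lists each had an adjusted p = 0.431 with an estimated correlation, as had MHC class II, where 13 of 15 rose (13 adjusted over the list alone; median 1.55, camera adjusted p 1.31e-08), and MHC class I, where 11 of 14 rose (11 adjusted over the list alone; median 0.83, camera adjusted p 2.53e-06). Immediate early genes rose in 18 of 27 cases and fell in 3 (21 and 3 adjusted over the list alone; median 1.38, camera adjusted p 1.58e-07; adjusted p = 0.266 with an estimated correlation), JUN by 3.58 ± 0.25 SE and JUNB by 2.45 ± 0.14 SE. Histone genes rose in 16 of 46 cases and fell in 0 (16 and 0 adjusted over the list alone; median 0.99, camera adjusted p 4.15e-05; adjusted p = 0.293 with an estimated correlation). There were 8, 10 and 10 rises without KO GSK595 replicate 1, WT GSK595 replicate 1 and WT GSK595 replicate 2.

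Replication genes fell most widely among the growth lists: 33 of 40 genes of G1/S and DNA replication fell and 0 rose (35 and 1 adjusted over the list alone; median -0.70, camera adjusted p 1.49e-09; adjusted p = 0.51 with an estimated correlation). Among them were the primase gene PRIM1 (-1.08 ± 0.12 SE), GINS2 (-1.05 ± 0.12 SE) and RFC4 (-1.01 ± 0.10 SE). Repair genes of the Fanconi and homologous recombination pathways fell in 19 of 35 cases and rose in 3 (20 and 3 adjusted over the list alone; median -0.42, camera adjusted p 0.00083; adjusted p = 0.579 with an estimated correlation), while BRCA2 rose (1.09 ± 0.09 SE). Of the G2/M and mitosis genes 15 of 40 fell and 0 rose (15 and 0 adjusted over the list alone; median -0.33, camera adjusted p 6.93e-05; adjusted p = 0.629 with an estimated correlation). Cytosolic ribosomal protein genes fell in 29 of 77 cases (32 adjusted over the list alone; median -0.21, camera adjusted p 4.74e-07; adjusted p = 0.629 with an estimated correlation). Without KO GSK595 replicate 2 and WT GSK595 replicate 1, 18 and 17 replication genes, 12 and 11 repair genes and 9 and 9 mitotic genes fell, with 1 and 1 repair genes rising. And 1 repair gene rose also without KO GSK595 replicate 1 or WT GSK595 replicate 2. Without KO GSK595 replicate 1, WT GSK595 replicate 1 and WT GSK595 replicate 2, 10, 6 and 9 ribosomal protein genes fell.

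The m6A machinery passed as a list in GSK595: 10 of 21 genes rose and 0 fell (10 and 0 adjusted over the list alone; median 0.24, camera adjusted p 0.0309; adjusted p = 0.642 with an estimated correlation). YTHDF2 rose by 1.07 ± 0.13 SE, YTHDF3 by 0.58 ± 0.10 SE and WTAP, a methyltransferase adaptor, by 0.58 ± 0.10 SE. The call was lost without KO GSK595 replicate 1 (adjusted p 0.11, 6 rises) and without WT GSK595 replicate 2 (0.0674, 6 rises).

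The response to GSK595 was then compared between genotypes, by the interaction of KO and compound. It passed for 17 genes with a positive interaction, meaning a log2 fold change under GSK595 that was more positive or less negative in KO than in WT cells, and for 0 with a negative one. They included the interferon-induced genes DDX58 (interaction log2 fold change 2.62 ± 0.20 SE, edgeR adjusted p 0.00758) and IFIT5 (2.57 ± 0.21 SE, 0.00758), the NF-kB target TRAF1 (2.77 ± 0.27 SE, 0.0091), and the stress response genes ATF3 (3.64 ± 0.35 SE, 0.0091) and CHAC1 (3.81 ± 0.46 SE, 0.0307). ATF3 had fallen in WT cells and rose in KO cells under GSK595 (1.38 ± 0.24 SE). That rise was lost without KO DMSO replicate 1 (0.0734), KO DMSO replicate 2 (0.0588) or KO GSK595 replicate 2 (0.0609). CHAC1, already low in KO DMSO (2.37 ± 0.71 CPM, SD, n = 2), fell in KO cells as well, by less than in WT cells (-1.72 ± 0.34 SE). That fall was lost without KO DMSO replicate 2 (0.089), KO GSK595 replicate 1 (0.0804) or KO GSK595 replicate 2 (0.0617). At an unadjusted p under 0.05 there were 2206 genes. The 17 genes became 0 without KO DMSO replicate 1, WT GSK595 replicate 1 or WT GSK595 replicate 2 (1432, 1506 and 1691 genes at an unadjusted p under 0.05), 6 without KO DMSO replicate 2, 11 without KO GSK595 replicate 1, 4 without KO GSK595 replicate 2, 2071 without WT DMSO replicate 1 (1039 positive and 1032 negative) and 50 without WT DMSO replicate 2 (47 positive and 3 negative). They were 229 with the replicate number as a block (155 positive and 74 negative), 594 in DESeq2 (390 positive and 204 negative) and 96 with no filter on low counts (83 positive and 13 negative).

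Of the named interaction genes, DDX58 was lost without KO DMSO replicate 1 (adjusted p 0.0545), WT GSK595 replicate 1 (0.0609) and WT GSK595 replicate 2 (0.0557), and IFIT5 without those (0.0608, 0.0609 and 0.0557) and KO GSK595 replicate 2 (0.0535). TRAF1 was lost without KO DMSO replicate 1 (0.0819), KO DMSO replicate 2 (0.0663), WT GSK595 replicate 1 (0.0633) and WT GSK595 replicate 2 (0.0557). ATF3 was lost without KO DMSO replicate 1 (0.0819), KO DMSO replicate 2 (0.0608), KO GSK595 replicate 2 (0.0611), WT GSK595 replicate 1 (0.0633) and WT GSK595 replicate 2 (0.0557). CHAC1 was lost without KO DMSO replicate 1 (0.163), KO DMSO replicate 2 (0.0663), KO GSK595 replicate 1 (0.081), KO GSK595 replicate 2 (0.213), WT GSK595 replicate 1 (0.0633) and WT GSK595 replicate 2 (0.104).

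**Figure D4:**
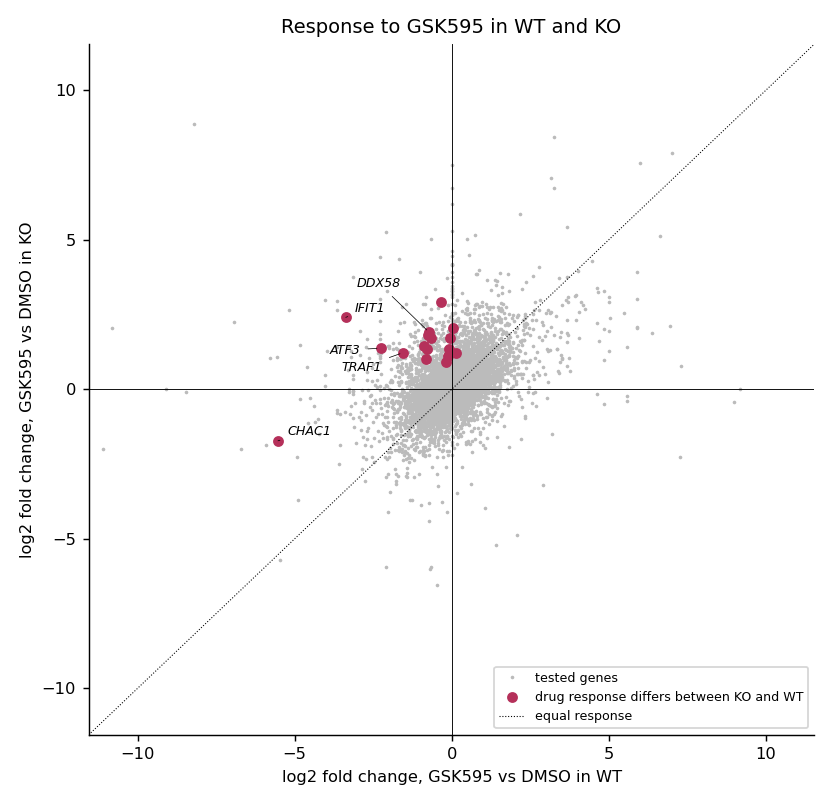
Log2 fold change under GSK595 in WT cells (horizontal axis) and KO cells (vertical axis) for the 14855 tested genes, with the 17 genes whose response differed between genotypes in red and a dotted line of equal response. All 17 lie above the line, and fitted values of genes with few counts in a group, IFIT1 among them, depend on the prior count.

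Genes called under GSK595 in both genotypes were compared by overlap. Of the genes called in each, 413 rose in both WT and KO cells, against 67.8 for independent lists, and 398 fell in both, against 72.3; 1 rose in WT and fell in KO, and 18 fell in WT and rose in KO. Across genes, which are not independent replicates, the responses in WT and KO cells had a Pearson r of 0.409 and a Spearman rho of 0.478. These comparisons share no library.

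Knockout in DMSO and compound in WT cells were both measured against the WT DMSO libraries. Of the genes called in each, 363 rose in both, against 117 for independent lists, and 392 fell in both, against 117, while 52 and 35 went in opposite directions. The fold changes had a Pearson r of 0.473 and a Spearman rho of 0.417 across genes, and unchanged groups simulated against the same control libraries gave a mean r of 0.497 over 20 runs. The covariance was 0.329, against a simulated 0.0885 ± 0.006 (SD over runs), a difference of 0.24. The simulation drew genes independently and gave a gene the same dispersion in every group. The real WT DMSO replicates differed more than those of other groups (chi-square per degree of freedom 189 against 43.0 to 58.9). By the SD of their log2 differences across genes the gap was milder, at 0.579 against 0.47 to 0.528. Noise in these shared controls can therefore exceed the simulated value, by an amount that was not tested. The difference cannot be read as a likeness of KO and compound. Comparisons with a common control move together by construction. A division of the 2 control libraries between the comparisons was not tried.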

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

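The tests of explanations given here were chosen only after the results were seen; the interaction test itself was planned.

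The response to GSK595 differed between KO and WT cells for 17 genes by the edgeR interaction test. The named ones had an interaction log2 fold change of 5.78 (IFIT1), 3.81 (CHAC1), 3.64 (ATF3), 2.77 (TRAF1), 2.62 (DDX58), 2.57 (IFIT5), 1.10 (TNFAIP3) and 1.08 (SP110). The IFIT1 value depends on the prior count, since the gene had 3 counts in WT GSK595. The count ratio of GSK595 over DMSO for IFIT1 was 0.0898 (95% interval 0.0177 to 0.286) in WT and 5.32 (5.07 to 5.59) in KO cells. SP110 was lost without KO DMSO replicate 1 (adjusted p 0.204), KO DMSO replicate 2 (0.264), KO GSK595 replicate 1 (0.0817), KO GSK595 replicate 2 (0.176), WT GSK595 replicate 1 (0.139) and WT GSK595 replicate 2 (0.088). TNFAIP3 was lost without the same 6 libraries (0.204, 0.31, 0.119, 0.253, 0.0633 and 0.14), and IFIT1 without KO DMSO replicate 1 (0.0545), WT GSK595 replicate 1 (0.0633) and WT GSK595 replicate 2 (0.0557).

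By camera with the preset correlation, 14 lists differed in their response. The interaction is the log2 fold change under GSK595 in KO minus that in WT cells. Its median was positive, at 1.31 (type I interferon response), 1.3 (integrated stress response), 1.10 (NF-kB targets), 0.84 (immediate early and AP-1 genes), 0.52 (MHC class I), 0.50 (MHC class II), 0.22 (BCL2 family) and 0.12 (G2/M and mitosis). Of these, the stress response list fell less in KO than in WT cells (medians -0.19 and -1.40), as did G2/M (-0.22 and -0.40). The median was negative for MYC targets and ribosome biogenesis (-0.44), G1/S and DNA replication (-0.42), plasmacytoid dendritic cell identity (-0.37), arginine methyltransferases and the PRMT5 complex (-0.29), Fanconi and homologous recombination repair (-0.17) and mitochondrial ribosomal proteins (-0.15). No list passed with an estimated correlation or by fry. Counted over all genes, 5 interferon, 2 NF-kB, 2 stress response and 1 immediate early gene had a positive interaction (22, 9, 21 and 13 adjusted over the list alone).

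Single libraries moved several of these lists. Without WT DMSO replicate 2 the medians of the stress response, NF-kB, MYC, PRMT5 complex and BCL2 lists were 0.62, 0.40, -0.27, -0.18 and 0.10. Without WT DMSO replicate 1 the PRMT5 complex, mitochondrial ribosomal, G2/M and BCL2 lists stood at -0.45, -0.22, 0.23 and 0.40, and without KO GSK595 replicate 1 the MHC class II and BCL2 lists at 0.77 and 0.39. The BCL2 list was at 0.11 without KO GSK595 replicate 2 and at 0.42 without WT GSK595 replicate 2, and G2/M was at 0.26 without KO GSK595 replicate 2. The BCL2 call was lost without KO DMSO replicate 1 (adjusted p 0.052), KO DMSO replicate 2 (0.054), KO GSK595 replicate 2 (0.0562), WT DMSO replicate 1 (0.0564) and WT GSK595 replicate 1 (0.104). The G2/M call was lost without KO DMSO replicate 2 (0.19), KO GSK595 replicate 1 (0.931, median 0.04), WT DMSO replicate 2 (0.225) and WT GSK595 replicate 1 (0.146), with gene-wise scaling factors (0.0869) and with the replicate number as a block (0.0554). The Fanconi call was lost without KO DMSO replicate 1 (0.167), KO GSK595 replicate 2 (0.248, median -0.10), WT DMSO replicate 2 (0.188) and WT GSK595 replicate 1 (0.284, median -0.09).

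Stress response genes were highest in WT DMSO, lower with KO or compound alone, and the list did not pass for GSK595 in KO cells. A single aberrant WT DMSO library was set against this: the lower of the pair still lay above the highest of the other 6 libraries by a median of 0.57 log2 CPM over the list (95% interval 0.41 to 0.83), which argues against it as the whole cause. Gene-wise scaling factors left the weaker of the 2 list medians at -1.44 (-2.23 to -1.06). This argues against the scaling only for members with a count in every library, since the others took the median factor of each library. The genes of this list had an estimated correlation of 0.774, so intervals over genes are too narrow. A different growth state of the WT DMSO cultures at harvest cannot be told apart from an effect of KO and compound: genes of glycolysis and hypoxia had a median of -0.28 (-0.88 to 0.09) for KO in DMSO and of -0.28 (-0.76 to -0.10) for GSK595 in WT, and the first interval includes 0. An effect of METTL3 loss and of PRMT5 inhibition on the stress response stays open as well.

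Interferon response genes were higher in KO cells in DMSO and higher again in GSK595. One KO library alone is argued against, since the lowest of the 4 KO libraries exceeded the highest of the 4 WT libraries by a median of 2.08 log2 CPM (95% interval over genes 1.24 to 2.56). Gene-wise factors gave a median of 3.03 (1.90 to 4.34 over genes) for KO in DMSO. This argues against the scaling only for members with a count in every library, since the others took the median factor of each library. The genes of this list had an estimated correlation of 0.472, so intervals over genes are too narrow. Interferon beta made by the cells may contribute to the further rise under GSK595: IFNB1 had 16 counts in KO DMSO and 150 in KO GSK595, a ratio of 9.88 (5.89 to 17.7). The intervals of count ratios cover counting alone and not the spread between replicates. The KO DMSO libraries had 2 and 14 IFNB1 counts. The ratio was 5.66 (3.27 to 10.6) without KO DMSO replicate 1 and 39.4 (10.7 to 329) without KO DMSO replicate 2. IFNL1, another interferon gene, went from 41 to 24 counts, a ratio of 0.617 (0.357 to 1.05), which was 0.396 without KO DMSO replicate 1, 1.4 without KO DMSO replicate 2 and 0.31 without KO GSK595 replicate 2. Whether IFNB1 differed between KO and WT cells in DMSO was not settled, the WT DMSO libraries having 0 and 6 counts. IFNL1 had 41 counts in KO DMSO and 3, near the floor, in WT DMSO, a ratio of 14.09 (4.497 to 71.15). That ratio was 21.95 without KO DMSO replicate 1, 6.204 without KO DMSO replicate 2 and 7.011 without WT DMSO replicate 1. Without WT DMSO replicate 2 no WT count was left, and the lower bound was 5.505. Whether IFNL1 contributed to the higher interferon response genes in DMSO was not tested. Whether the WT cells received tetracycline, and whether the KO line differed from the WT line before induction, are not in the labels and were not tested.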

How the results depend on the processing

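The gene-wise factors, and the list tests without single libraries, were chosen only after the results were seen. With a log2 fold change of at least 1 required, the counts were 1215 (KO in DMSO), 454 (GSK595 in WT), 630 (GSK595 in KO) and 1627 (KO in GSK595). With the groups compared alone, 2752 genes changed for KO in DMSO, 77 for GSK595 in WT and 3995 for GSK595 in KO. DESeq2 gave 2552 for GSK595 in WT and 594 for the interaction, and no filter gave 96 for the interaction. The replicate block gave 2799 for GSK595 in WT, 3966 for GSK595 in KO and 229 for the interaction. The cause of these shifts was not tested, apart from the fewer libraries or genes that a setting leaves.

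Leaving out single libraries gave 1703 to 5116 genes for KO in DMSO, 91 to 3262 for GSK595 in WT, 309 to 774 for GSK595 in KO, 2487 to 3360 for KO in GSK595 and 0 to 2071 for the interaction. METTL3 in DMSO ranged from -0.34 to -0.10 and passed only without WT DMSO replicate 2. With an estimated correlation, 0 lists passed for KO in DMSO, 0 for GSK595 in WT, 1 for GSK595 in KO, 0 for KO in GSK595 and 0 for the interaction, and fry called 13, 2, 8, 19 and 0 in the same order, against 12, 7, 17, 15 and 14 by camera with the preset correlation. In that order, fry kept 10, 2, 8, 14 and 0 of camera's calls in the same direction. With the stricter filter the correlation of the GSK595 responses was 0.565 and that of KO and GSK595 with a shared control 0.524.

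The block also called PRMT5 (-0.39, adjusted p 0.0206) and the Fanconi list (0.0421) for GSK595 in KO and the Sm and snRNP list for the interaction (0.0495), and lost the BCL2 list for KO in GSK595 (0.0626) and the G2/M list for the interaction (0.0554). It changed no other call of a named gene or list. Of 409 called results of named genes, 236 kept their call under every alternative run, 173 lost it under at least one and 0 reversed. The groups compared alone lost 63, gene-wise factors 14, no filter 7, RLE factors 2, thinning 2, the stricter filter 1 and DESeq2 1. By comparison, calls were lost for 31 of 115 (KO in DMSO), 51 of 63 (GSK595 in WT), 58 of 94 (GSK595 in KO), 25 of 129 (KO in GSK595) and 8 of 8 (interaction). Leaving out some library lost 31, 44, 58, 25 and 8 of these, and the groups compared alone lost 16 for KO in DMSO, 46 for GSK595 in WT and 1 for KO in GSK595. Gene-wise factors also changed 3 list calls: m6A passed for KO in DMSO (0.0371), and cholesterol synthesis for GSK595 in KO (0.0586) and G2/M for the interaction (0.0869) were lost. Thinning to the shallowest library moved no count of changed genes by more than a factor of 1.5. The library totals were close to each other, so a larger change of depth was not tested.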

Other observations

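The tests of explanations given here were chosen only after the results were seen.

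For KO in DMSO, members of some lists moved in both directions. Of 26 genes of the unfolded protein response 9 rose and 5 fell (10 and 6 adjusted over the list alone; camera adjusted p 0.358), HSPA5, the main chaperone of the endoplasmic reticulum, rising by 1.10 ± 0.15 SE while XBP1 (-1.29 ± 0.19 SE), HERPUD1 (-1.33 ± 0.20 SE) and DERL3 (-1.35 ± 0.17 SE) fell. Of 18 genes of the BCL2 family 6 rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p 0.29), BCL2L1 standing at 0.84 ± 0.10 SE and BCL2 at -1.37 ± 0.17 SE; 3 rose without KO DMSO replicate 1 or KO DMSO replicate 2. For KO in GSK595, 7 of these rose and 1 fell (7 and 1 adjusted over the list alone), and the list was called as higher (camera adjusted p 0.0483; adjusted p = 0.434 with an estimated correlation). That call was lost without KO GSK595 replicate 2 (0.0656) or WT GSK595 replicate 1 (0.101) and with the replicate number as a block (0.0626). BCL2L1 was at 1.34 ± 0.10 SE, MCL1 at 1.05 ± 0.09 SE and BCL2 at -1.52 ± 0.17 SE. Without KO DMSO replicate 1, 4 genes of the unfolded protein response rose and 4 fell, without KO DMSO replicate 2 it was 5 and 3, and 6 rose without WT DMSO replicate 2.

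Markers of monocytes, macrophages and conventional dendritic cells were higher in KO cells. Monocytes in the KO cultures are argued against: the summed counts of 6 abundant monocyte transcripts reached at most 0.0326% of the LYZ count in a KO library, whereas monocytes would bring them all. The median of the list exceeded that of B lymphoid markers by 1.87 on the log2 scale (95% interval over genes 0.69 to 3.45). A lower share of the main cell type cannot be decided from this, since B lymphoid markers would rise only if the other cells expressed them. Among genes of plasmacytoid dendritic cell identity 10 of 34 rose and 8 fell in the same comparison (13 and 9 adjusted over the list alone; median 0.29, camera adjusted p 0.29), and fry called the list as higher (adjusted p 0.0491). There were 7 rises and 3 falls without KO DMSO replicate 1, and 6 and 3 without KO DMSO replicate 2. For KO in GSK595, 8 of the 34 identity genes rose and 10 fell (9 and 11 adjusted over the list alone, median -0.27, camera adjusted p 0.454). There fry called the identity list as lower (adjusted p 0.0346), so its direction was not the same in DMSO and GSK595. A change of state of the CAL-1 cells stays open, and other dendritic cells were not tested for. CD1C, a marker of conventional dendritic cells that was picked after its values were seen, had 41263 counts in WT DMSO and 159645 in KO DMSO.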
